A study of Mus musculus with 2 samples.

How the data were processed

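RNA of innate lymphoid cells of group 2 (ILC2) at the progenitor stage was measured by RNA sequencing in 2 libraries of 1 group. Per the labels, the cells were sorted by flow cytometry from bone marrow of C57BL/6 mice 8 weeks of age, each library came from a pool of 8 mice, and 100 ng of total RNA from the RNeasy Micro kit entered the Illumina TruSeq RNA preparation. The antibodies of the sort and the sex of the mice are not given in the sources used here. The libraries are called pool 1 and pool 2 in accession order, which carries no other meaning. The column heading inside each file carries the sample code of the other library, so 0 of 2 headings matched their own sample. Each file was assigned to the sample it was deposited under, and if the headings are right, pool 1 and pool 2 exchange their names in every difference below.

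The authors deposited length- and depth-normalised read values (RPKM) for 27179 Entrez gene IDs in each library. The submitters' processing notes name CASAVA 1.8.2, featureCounts with no version, edgeR 3.8.2 and edgeR 3.22.0 and the mm10 build, without saying which step each served, and the aligner and strand setting are not given in the sources used here. Gene names were taken from the files. Of these rows, 515 have no symbol and 27 carry a spreadsheet date in place of one, and 25275 IDs matched the reference gene table of the same build, from which coordinates were taken.

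The planned tests assumed read counts. Since the deposited values are RPKM, the count models were replaced: thresholds planned in CPM were applied to RPKM, the deposited scaling was the main one, and genes were called apart between the libraries by fold alone. Whole reads were looked for in the steps between RPKM values. Library totals of 20216146 and 19834586 reads were found, and for 17233 of 17233 genes above 0 in either library (100%) a whole gene length between 20 and 130000 bases gave whole reads in both libraries within the rounding of the deposited values. With totals wrong by 1 part in 1000, 0.40% of 1000 genes did so, drawn only from genes above 0 in both libraries. These reads are lower bounds, because a multiple of the length also fits, and they sum to 90.0% and 89.8% of the totals. They were used for an exact binomial test, for a coefficient of variation over counting noise and for alternatives. For values in CPM, the length was multiplied where it lay under 40% of the annotated exon length, and these sum to 100.6% of either total.

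A gene was called detected at 1 RPKM or more in both libraries. Levels were log2(RPKM + 0.1) averaged over the libraries, ratios were taken on the same scale, which understates the difference of low genes, and correlations used log2(RPKM + 1). The text covers 24 gene lists holding 377 genes: ILC2 transcription factors, ILC2 surface receptors, type 2 effectors, ILC precursor genes, 10 lists of other cell lineages, cell cycle, nuclear receptors, Notch pathway, homing receptors, cytokine receptor and JAK-STAT genes, immediate early and stress genes, interferon-stimulated genes, co-stimulatory and inhibitory receptors, neuropeptide and lipid mediator genes, and Y-linked genes with Xist. Some genes are on more than 1 list, and 3 erythroid genes (Hbb-bt, Hbb-b2 and Ahsp) were not analysed here. Ptgdr2, Jchain and Siglecf were matched by ID to the older symbols Gpr44, Igj and Siglec5.

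A list's level was the median over its members, placed among 10000 random lists of the same size. These were drawn from all 27179 genes, of which 17233 were above 0 in either library. A high percentile therefore partly reflects being expressed at all. The ILC2 transcription factors and surface receptors, 32 genes together, were compared with each of 10 other lineage lists by a two-sided permutation test of gene labels on the difference of medians (100000 resamples, Benjamini-Hochberg adjustment over the 10 comparisons). These p-values concern genes within the libraries, and genes are not independent replicates. A list's shift between the libraries was the median log2 ratio of its detected members, placed among 10000 random lists matched on mean expression in 20 bins, and a list was counted as apart below the 2.5th or above the 97.5th percentile. With 1 library a side, these percentiles describe the libraries and are no p-values. Intervals over genes came from 500 bootstrap draws.

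The gene lists, the comparisons, most alternatives and the rule for named genes were set before the data were examined. The rule takes a fixed set of regulators, receptors and cytokines, the 10 most abundant genes, the 3 highest and the 1 lowest member of each list, and, among genes 2-fold apart with a mean of 5 RPKM or more and an adjusted p under 0.05 in the exact binomial test, the 6 with the largest ratio in each direction. Some genes that the rule takes are not reported here, and other genes in the text were chosen after their values were seen. Shares are of summed RPKM, for which no binomial interval holds. The alternatives were other filters (0.5 and 5 RPKM, 10 reads, 1 RPKM in either library, none), scalings by trimmed mean (30% of ratios and 5% of levels trimmed at each end), median of ratios and upper quartile, pseudocounts of 0.01 and 1, CPM in place of RPKM, other summaries of a list, and each library left out in turn.

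The calculations were tested on simulated reads for the genes of these libraries, with 200 genes changed by known folds and a coefficient of variation of 0.15. In the simulated comparison of pool 2 with pool 1, on 6108 genes, both totals were recovered with a difference of 0 reads and the coefficient of variation came out at 0.147. The 2-fold rule called 72.0% of genes changed 2.5-fold, 100% of those changed 4-fold, 100% of those changed 8-fold and 11 of 4125 unchanged genes. The binomial test passed 51.7% of the unchanged genes, since it covers counting error only. The coefficients measured in the data, 0.198 from RPKM ratios and 0.172 from recovered reads, exceed the simulated 0.15. The 11 calls therefore do not give the rate of false calls in these libraries. Changed genes were drawn only from those at 5 RPKM or more in both libraries, whereas the rule was applied from 1 RPKM. Of 2000 random pairs of lists, 5.35% had a permutation p under 0.05. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.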

Results

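The transcriptome of ILC2 progenitors, the bone marrow precursors of the innate lymphocytes that make type 2 cytokines, was measured in 2 libraries, each from a pool of 8 mice. No other group was part of the data, so the comparisons are between gene programs within these cells and between the 2 pools. The depth was 20216146 reads for pool 1 and 19834586 for pool 2, at which 3 reads in a gene of 1 kb equal 0.148 and 0.151 RPKM. In pool 1, 11256 genes reached 1 RPKM and in pool 2 11429 did, with 11013 in both. Means are given with the SD over the pools (n = 2).

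The first comparison asked how strongly the sorted cells expressed the ILC2 program. Gata3, the transcription factor that ILC2 depend on (Entrez ID 14462, chromosome 2, 9857078 to 9887953, mm10), was at 271 ± 29.8 RPKM. Other factors of ILC2 development were also abundant: Id2, an inhibitor of E proteins, at 498 ± 299 RPKM, Ets1 at 282 ± 19.1, Lmo4 at 278 ± 31.6, Tcf7 at 79.5 ± 23.9, Gfi1 at 41.4 ± 9.15, the orphan nuclear receptor Rora at 53.7 ± 3.31 and Bcl11b at 28.2 ± 2.66. Zbtb16, which encodes PLZF and marks earlier ILC precursors, was the lowest of the list at 4.83 ± 0.942 RPKM. All 15 listed ILC2 transcription factors were detected, and their median level of 5.44 (log2) lay above that of every one of 10000 random lists. Since the random lists include genes without reads, this is not particular to ILC2 genes. The T cell and neutrophil lists also lay above all of them, and the erythroid list was at the 99.9th percentile. Id2 differed most between the pools among the factors at 100 RPKM or more, at 709.7 RPKM in pool 1 and 287 in pool 2.

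ILC2 surface receptors were higher still, with a median of 7.39 (log2), 11 of 17 members at a mean of 100 RPKM or more and a level above all 10000 random lists. Ly6a, which encodes Sca-1, stood at 1160.4 ± 224 RPKM, the common cytokine receptor chain Il2rg at 700.5 ± 54.6, Thy1 at 534 ± 33.7 and the IL-7 receptor Il7r at 411 ± 77.9. The receptors for the alarmin cytokines IL-33 and IL-25 were at 218 ± 62.4 RPKM (Il1rl1) and 199 ± 4.33 RPKM (Il17rb). Tnfrsf18 was at 271 ± 50.5, the neuromedin U receptor Nmur1 at 206 ± 17.6, the co-stimulator Icos at 168 ± 2.03, Il2ra at 151 ± 6.73 and Klrg1, a receptor of mature ILC2, at 90.0 ± 22.8 RPKM. Gpr44, the prostaglandin D2 receptor CRTH2, was the lowest at 0.299 RPKM in pool 1 and 1.60 in pool 2.

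Type 2 effectors were unevenly expressed, with a list median of 1.58 (log2; 88.6th percentile of random lists). Arg1, the arginine-degrading enzyme, reached 366 ± 52.1 RPKM and Csf2, which encodes GM-CSF, 42.4 ± 10.1. The cytokine genes Il4, Il13 and Il5 were lower, at 12.3 ± 0.709, 5.02 ± 1.78 and 2.37 ± 1.35 RPKM, and Areg, an epidermal growth factor family ligand, was at 4.19 ± 2.42. Il3 and Il9 were listed at 0 in both pools. ILC precursor genes, all 14 of which are also on other lists, had a median of 4.40 (99.9th percentile), led by the integrin chain Itgb7 at 627 ± 2.15 RPKM and the chemokine receptor Cxcr6 at 607 ± 173. The stem cell factor receptor Kit was at 16.6 ± 7.77, Cxcr5 at 2.40 ± 0.154 and Flt3, a receptor of early progenitors, at 1.08 ± 0.526 RPKM.

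**Figure D1:**
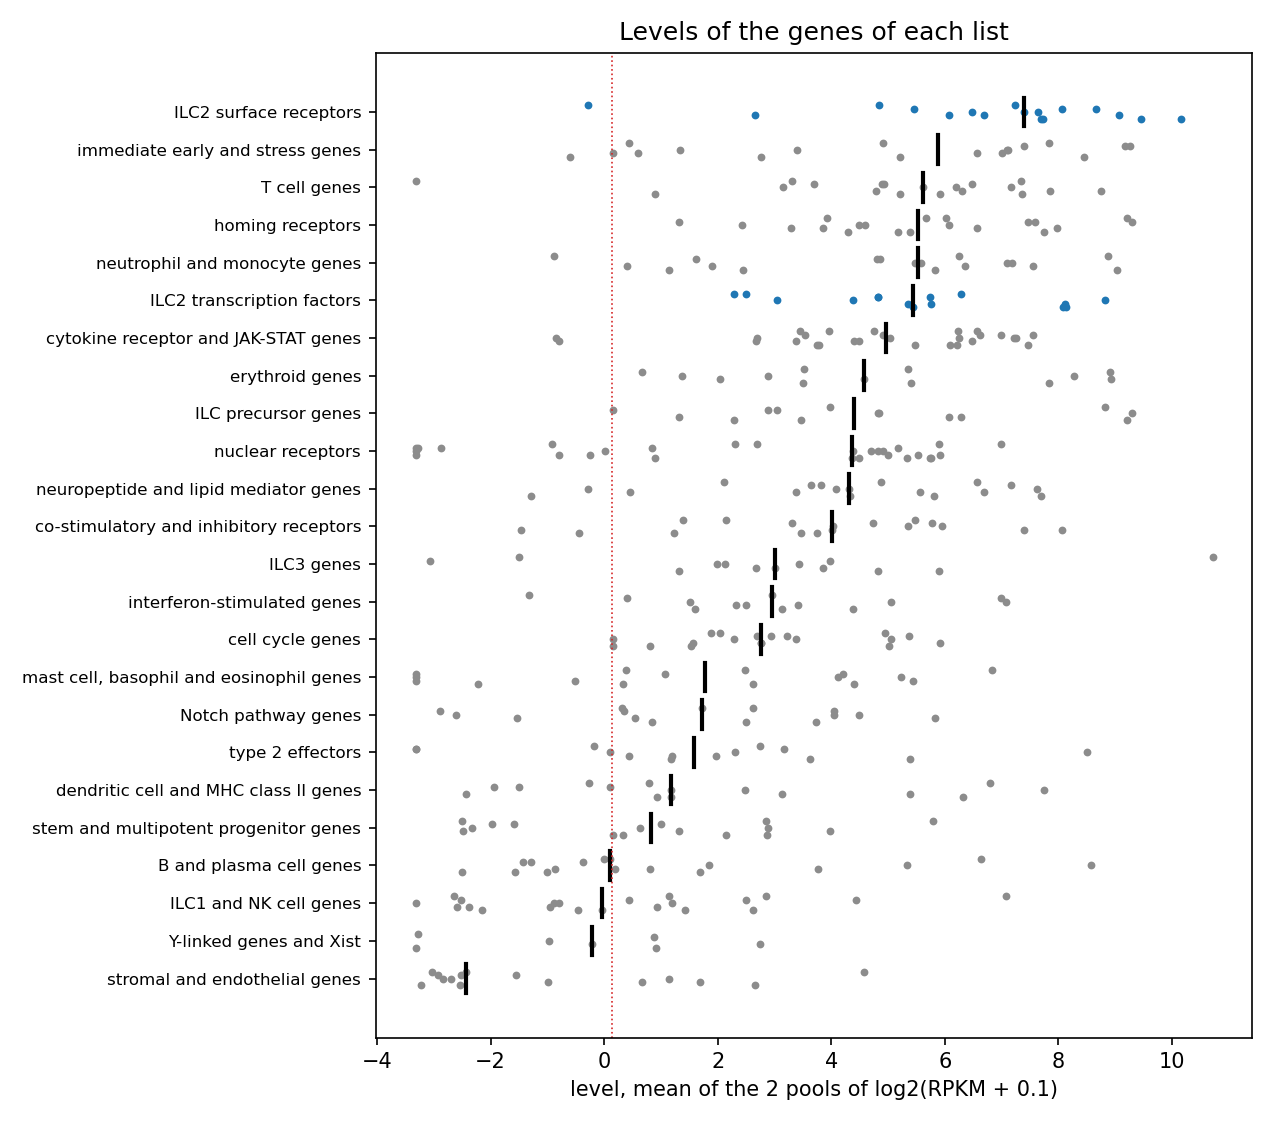
Level of each member of the gene lists, as the mean over the 2 pools of log2(RPKM + 0.1). Each point is a gene, the vertical bar is the list median, blue marks the ILC2 lists and the dotted line marks 1 RPKM. ILC2 surface receptors have the highest median (7.39) and stromal and endothelial genes the lowest (-2.44).

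The next comparison set the 32 ILC2 identity genes, with a median of 6.38 (log2), against marker genes of 10 other lineages. They were higher than the markers of ILC1 and NK cells by 6.42 ± 0.50 (log2, SD, n = 2 pools), of B and plasma cells by 6.27 ± 0.35, of stem and multipotent progenitor cells by 5.56 ± 0.42, of dendritic cells and MHC class II by 5.20 ± 0.29, of mast cells, basophils and eosinophils by 4.60 ± 0.25, and of stromal and endothelial cells by 8.81 ± 0.0049. The adjusted permutation p was 5e-05 for ILC1 and NK, stem, mast cell and stromal genes, 8e-05 for B cell genes and 0.000283 for dendritic cell genes. For ILC1 and NK genes and for stromal genes the unadjusted p of 1e-05 is the smallest the permutations can give. The difference from ILC3 genes was 3.36 ± 0.0062 (adjusted permutation p = 0.00181). Each of these 7 differences had the same sign in both pools. The antibodies of the sort are not given, so listed surface receptors may be high because the cells were selected on some of them. The mast cell and stromal differences taken within single pools were 5.20 and 4.84, and 8.62 and 8.63, since a median of averaged levels need not lie between the medians of the pools.

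T cell, neutrophil and erythroid genes were not separated from the ILC2 identity genes by this test. The T cell list lay lower by 0.76 ± 0.36 (adjusted permutation p = 0.332), with transcripts of the T cell receptor constant regions Trbc2 and Trbc1 at 432 ± 7.55 and 166 ± 23.5 RPKM, the adaptor Lat at 229.9 ± 12.3 and Cd3e, a chain of the T cell receptor complex, at 62.0 ± 23.0. Cd8a was listed at 0. The neutrophil and monocyte list lay lower by 0.85 ± 0.21 (adjusted permutation p = 0.332), with the calprotectin genes S100a9 and S100a8 at 583 ± 366 and 521 ± 330.0 RPKM and Ngp, a neutrophil granule gene, at 206 ± 120.2, while Cd14 was at 0.450 ± 0.112. The erythroid list lay lower by 1.79 ± 0.030 (adjusted permutation p = 0.211), with the globin genes Hba-a2, Hbb-b1 and Hbb-bs at 557 ± 386, 541 ± 359.9 and 351 ± 234 RPKM. In CPM, which do not divide by gene length, the 3 differences were 1.46, 2.61 and 2.64 with adjusted permutation p of 0.00898, 0.00279 and 0.00833. With the transcription factors alone, the T cell and neutrophil differences turned to -0.18 and -0.090 (adjusted permutation p = 1 for both), and with the surface receptors alone the T cell, neutrophil and erythroid differences were 1.77, 1.87 and 2.81 and passed (adjusted permutation p = 0.0473, 0.041 and 0.035).

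The other lineage lists held few abundant genes. In the ILC1 and NK list, 10 of 21 members were under 1 RPKM in both pools, Ccl5 was at 135 ± 2.56 RPKM, Nkg7 at 22.9 ± 10.6, Prf1 at 7.09 ± 0.422 and the NK receptor Ncr1 at 2.29 ± 0.996, and Klrc2 was listed at 0. Ltb, which encodes lymphotoxin beta, led the ILC3 list at 1685 ± 141 RPKM, ahead of Tnfsf11 at 59.8 ± 7.30, and Il17a was at 0 reads in pool 1 and 1 read in pool 2. In the B and plasma cell list, the immunoglobulin genes Ighm and Igkc stood at 380.2 ± 47.0 and 127 ± 111 RPKM and Cd79b at 40.7 ± 10.1, and Ebf1 was at 0.0220 and 0.157 RPKM in pools 1 and 2. Prg2 led the mast cell, basophil and eosinophil list at 249 ± 314 RPKM, from 27.2 in pool 1 and 471 in pool 2. Cpa3 was at 43.8 ± 9.02 RPKM and Prss34 at 37.8 ± 6.72. The MHC class II genes H2-Aa and H2-Ab1 were at 118 ± 58.2 and 83.2 ± 35.0 RPKM and the invariant chain Cd74 at 215 ± 20.7. In the stem cell list Hlf was highest at 55.2 ± 5.69 RPKM, and Pecam1 was at 23.8 ± 3.75 in the stromal list.

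Gata3 exceeded Tbx21 and Eomes, the factors that define ILC1 and NK cells, in both pools. Its log2 ratio was 7.37 and 5.96 to Tbx21 (mean 6.66 ± 1.0, n = 2) and 10.67 and 10.66 to Eomes (10.67 ± 0.0020). Tbx21 was at 1.67 and 3.93 RPKM and Eomes at 0.0799 and 0.0543 RPKM in pools 1 and 2. With n = 2 the smallest p an exact sign-flip test can give is 0.5, so no test was made. The Eomes ratio is set by the pseudocount, and was 11.80 with 0.01 and 7.99 with 1.

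Among the signalling lists, nuclear receptors had a median of 4.37 (log2; above all random lists). Rarg was at 126 ± 9.93 RPKM, Nr1h2 at 60.6 ± 6.05 and the glucocorticoid receptor Nr3c1 at 59.5 ± 8.81, against 0.496 ± 0.206 for the oestrogen receptor Esr1 and 0 for Rorb in both pools. Homing receptors had a median of 5.53 (above all random lists), with Ccr9, which directs cells to the small intestine, at 252 ± 17.4 RPKM and all 20 members detected. Cytokine receptor and JAK-STAT genes had a median of 4.97 (above all random lists), with Ifngr1 at 195 ± 75.1, Jak1 at 177 ± 13.5 and the feedback inhibitor Cish at 159 ± 61.6, and Il13ra1 lowest at 0.466 ± 0.137. Co-stimulatory and inhibitory receptors had a median of 4.01 (99.9th percentile), with Tnfrsf25 at 61.6 ± 3.52 and Cd244 lowest at 0.266 ± 0.0788. Neuropeptide and lipid mediator genes had a median of 4.32 (99.99th percentile), with the leukotriene B4 receptor Ltb4r1 at 199 ± 29.4, the leukotriene-forming enzyme Alox5 at 146 ± 34.5 and Ptgs2 at 0.313 ± 0.0468 RPKM.

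Cell cycle genes had a median of 2.75 (97.9th percentile). The replication genes Pcna, Mcm3 and Mcm2 were at 60.7 ± 7.01, 41.4 ± 4.22 and 33.3 ± 3.17 RPKM, while the proliferation marker Mki67 was at 1.68 ± 0.461 and the mitotic kinase gene Bub1 at 1.13 ± 0.740. Interferon-stimulated genes had a median of 2.95 (96.2nd percentile), with Bst2 at 135 ± 2.51, Irf7 at 33.4 ± 4.95 and Mx1 at 0.325 ± 0.201 RPKM. Notch pathway genes had a median of 1.73 (88.9th percentile), with Notch2 at 57.0 ± 4.33, Numb at 22.6 ± 3.76, the mediator Rbpj at 16.6 ± 2.16 and Notch4 at 0.0340 ± 0.00489. Immediate early and stress genes had a median of 5.89 (above all random lists), carried by pool 1, where the median was 7.97 against 3.64 in pool 2.

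The most abundant transcripts were those of antigen presentation, mitochondria and ribosomes. B2m, the light chain of MHC class I, was first at 8447 ± 241 RPKM, followed by the mitochondrial genes COX1 at 6923 ± 474 and CYTB at 5332 ± 504, Rpl8 at 3915 ± 328, H2-K1 at 3848 ± 52.8, Rplp1 at 3646 ± 575, ND1 at 3602 ± 117, ND2 at 3546 ± 1157, Eef1a1 at 2713 ± 71.6 and Rps15 at 2447 ± 406. These 10 genes held 9.26% of the summed RPKM in either pool. Mitochondrially encoded genes held 5.48% in pool 1 and 6.49% in pool 2, ribosomal protein genes 9.70% and 8.25%, haemoglobin genes 0.184% and 0.530%, immunoglobulin genes 0.253% and 0.109%, and ribosomal RNA genes 0.282% and 0.285%. As shares of estimated reads, which do not divide by gene length, these were lower, at 5.92% and 5.77% for the 10 genes, 2.99% and 3.42% for mitochondrially encoded, 4.10% and 3.48% for ribosomal protein, 0.053% and 0.15% for haemoglobin, 0.0831% and 0.0549% for immunoglobulin and 0.131% and 0.135% for ribosomal RNA genes.

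The last comparison asked how far the 2 pools differed. Across the 11013 detected genes, Pearson's r was 0.979 (95% bootstrap interval over genes 0.976 to 0.981) and Spearman's rho 0.979, where genes are not independent replicates. Of these genes, 91.5% lay within 1.5-fold, and 282 were at least 2-fold apart, 176 of them higher in pool 2 and 106 higher in pool 1. The coefficient of variation was 0.198 from the RPKM ratios (interval 0.189 to 0.210) and 0.172 from the recovered reads. The exact binomial test with Benjamini-Hochberg adjustment, which compares these 2 libraries and not conditions, passed 253 of the 2-fold genes. It covers counting error only and passed 5013 of all detected genes (45.5%), so passing it adds little to the fold. The difference between the pools has no replicate check, and the number of genes apart ranged from 81 to 1535 with the filter and test.

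Pool 1 was higher in genes that stimulated cells induce within minutes. Egr1 (chromosome 18, 34861207 to 34864956) was 89.2-fold higher, at 348 against 3.81 RPKM, Fos 49.1-fold at 2441 against 49.6, Fosb 35.9-fold, the phosphatase gene Dusp1 28.9-fold and Zfp36, which encodes an RNA-destabilising protein, 23.1-fold at 2786 against 120.3 RPKM. Of the 15 detected immediate early and stress genes, 14 were higher in pool 1 and 13 at least 2-fold, with Junb at 1969.6 and 189.7 RPKM. Their median log2 ratio of -3.22 lay below all 10000 matched random lists. The nuclear RNAs Malat1 and Neat1 were also higher in pool 1, each 2.29-fold. Hspa1a, a heat shock gene on the same list, was at 0.407 RPKM in pool 1 and 0.757 in pool 2. The immunoglobulin kappa segment Igkj2 had 148 reads in pool 1 and 2 in pool 2, a ratio of 72.6 (95% counting interval 19.7 to 605), and Igkc was 4.24-fold higher in pool 1. The bone matrix collagens Col1a1 and Col1a2 were at 40.5 and 18.7 RPKM in pool 1 against 0.889 and 0.451 in pool 2, below the detection threshold there.

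Pool 2 was higher in genes of eosinophil granules and in the T cell receptor gamma segment Tcrg-V6. Epx, the eosinophil peroxidase (chromosome 11, 87863997 to 87875536), was 29.6-fold higher at 33.3 against 1.03 RPKM, the granule proteins Prg2 17.3-fold at 471 against 27.2 and Prg3 13.9-fold, and the ribonuclease gene Ear6 9.53-fold. Ear genes form a family of near-identical copies, so reads may be split among them. Other eosinophil markers did not rise to the same degree. Ccr3 was at 4.61 RPKM in pool 1 and 6.56 in pool 2, and Siglec5 and Il5ra were under 1 RPKM in both. Of the 9 detected members of the mast cell, basophil and eosinophil list, 6 were higher in pool 2 and 3 in pool 1. The 3 were Mcpt8, Prss34 and Fcer1a, none of them among the eosinophil granule genes above. The 6 included Ear1 and Ear2, 3.39-fold and 3.49-fold higher, and Cpa3, 1.34-fold higher. Tcrg-V6 (chromosome 13, 19190368 to 19190929) was 39.3-fold higher, with 6 reads in pool 1 and 247 in pool 2, whereas the gamma constant regions Tcrg-C1 and Tcrg-C4 were at 506 and 675 RPKM in pool 1 against 359 and 422 in pool 2, and the less abundant Tcrg-C2 at 57.4 against 102. Cd163l1, a scavenger receptor family gene, was 15.2-fold higher at 43.7 against 2.78 RPKM.

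**Figure D2:**
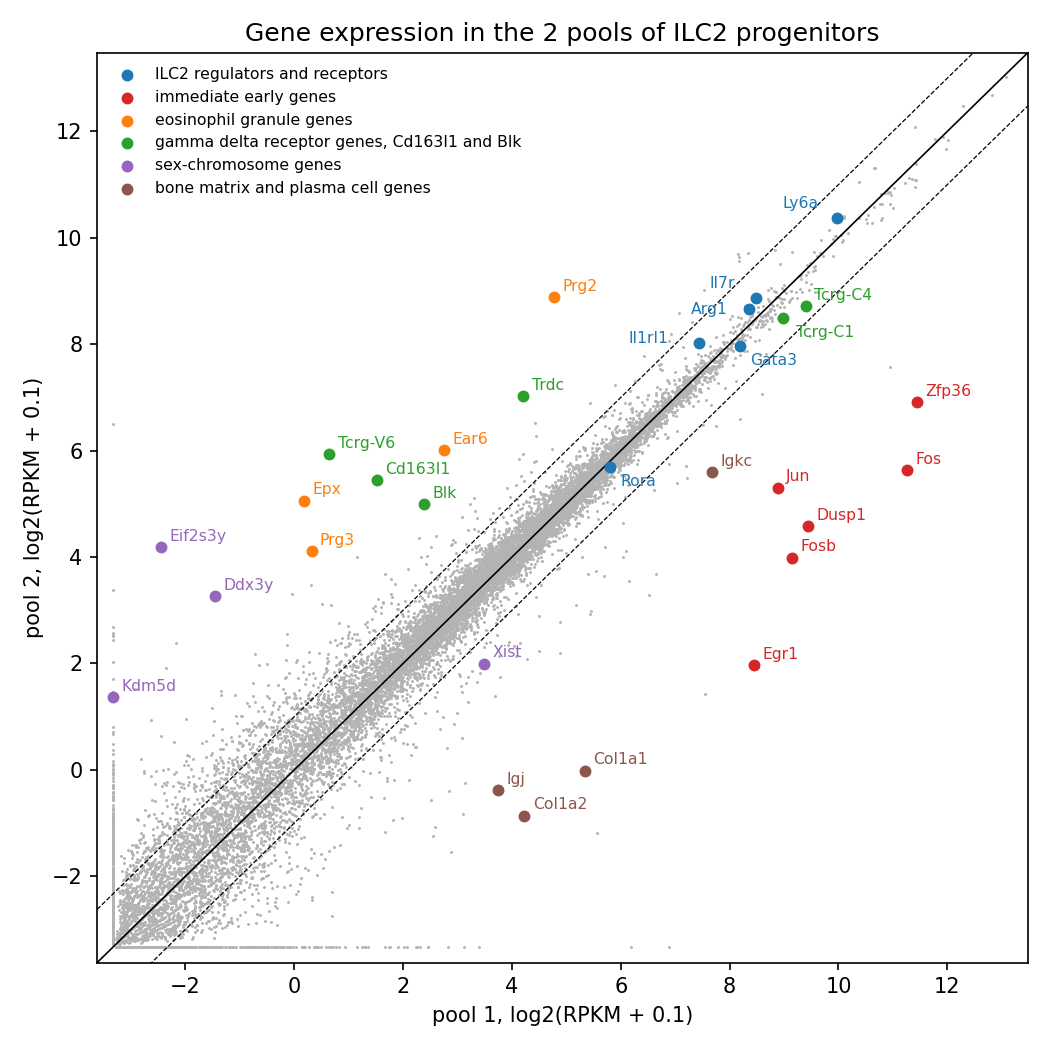
Expression of each gene in pool 1 (horizontal) and pool 2 (vertical), both as log2(RPKM + 0.1). Each point is a gene, the solid line is equality and the dashed lines are 2-fold differences, with colours for the gene groups in the key. Egr1 lies 89.2-fold toward pool 1 and Tcrg-V6 39.3-fold toward pool 2, while Gata3 and Rora lie within the dashed lines.

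As lists, 16 of 24 stood apart from matched random lists, 14 toward pool 2 and 2 toward pool 1. The 2 toward pool 1 were the immediate early list and the Y-linked list, of which only Xist was detected. Toward pool 2, erythroid genes had a median log2 ratio of 1.04 (11 of 12 detected members higher), ILC1 and NK genes 0.88, stem and progenitor genes 0.84, neutrophil and monocyte genes 0.83 (15 of 16 higher), cell cycle genes 0.78 (17 of 17), B and plasma cell genes 0.69, ILC3 genes 0.54, mast cell, basophil and eosinophil genes 0.50, dendritic cell genes 0.40, ILC precursor genes 0.39, interferon-stimulated genes 0.38 (12 of 12), T cell genes 0.28, homing receptors 0.27 and ILC2 surface receptors 0.10. The ILC2 transcription factors had a median of 0.14 (96.1st percentile), type 2 effectors 0.12, cytokine receptor genes 0.04, neuropeptide and lipid mediator genes 0.04, nuclear receptors -0.02, Notch genes -0.09 and co-stimulatory receptors -0.09, and the 1 detected stromal gene 0.32, all within the random lists. With genes at 5 RPKM or more, the medians of ILC1 and NK, ILC3 and B cell genes lay within the random lists at 0.041, 0.25 and 0.13, as did dendritic cell genes at 10 reads (0.23) and ILC2 surface receptors matched on gene length as well (0.098). Stromal genes stood apart toward pool 1 at -2.52 with a filter of 0.5 RPKM, the midpoint of 2 genes in opposite directions, Col1a1 at -5.36 and Pecam1 at 0.32. They also did at 10 reads (-2.28), where Col1a2 at -5.09 and Sparc at -3.94 join, along with Cxcl12 at -0.62 and Pdgfrb at 1.75.

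**Figure D3:**
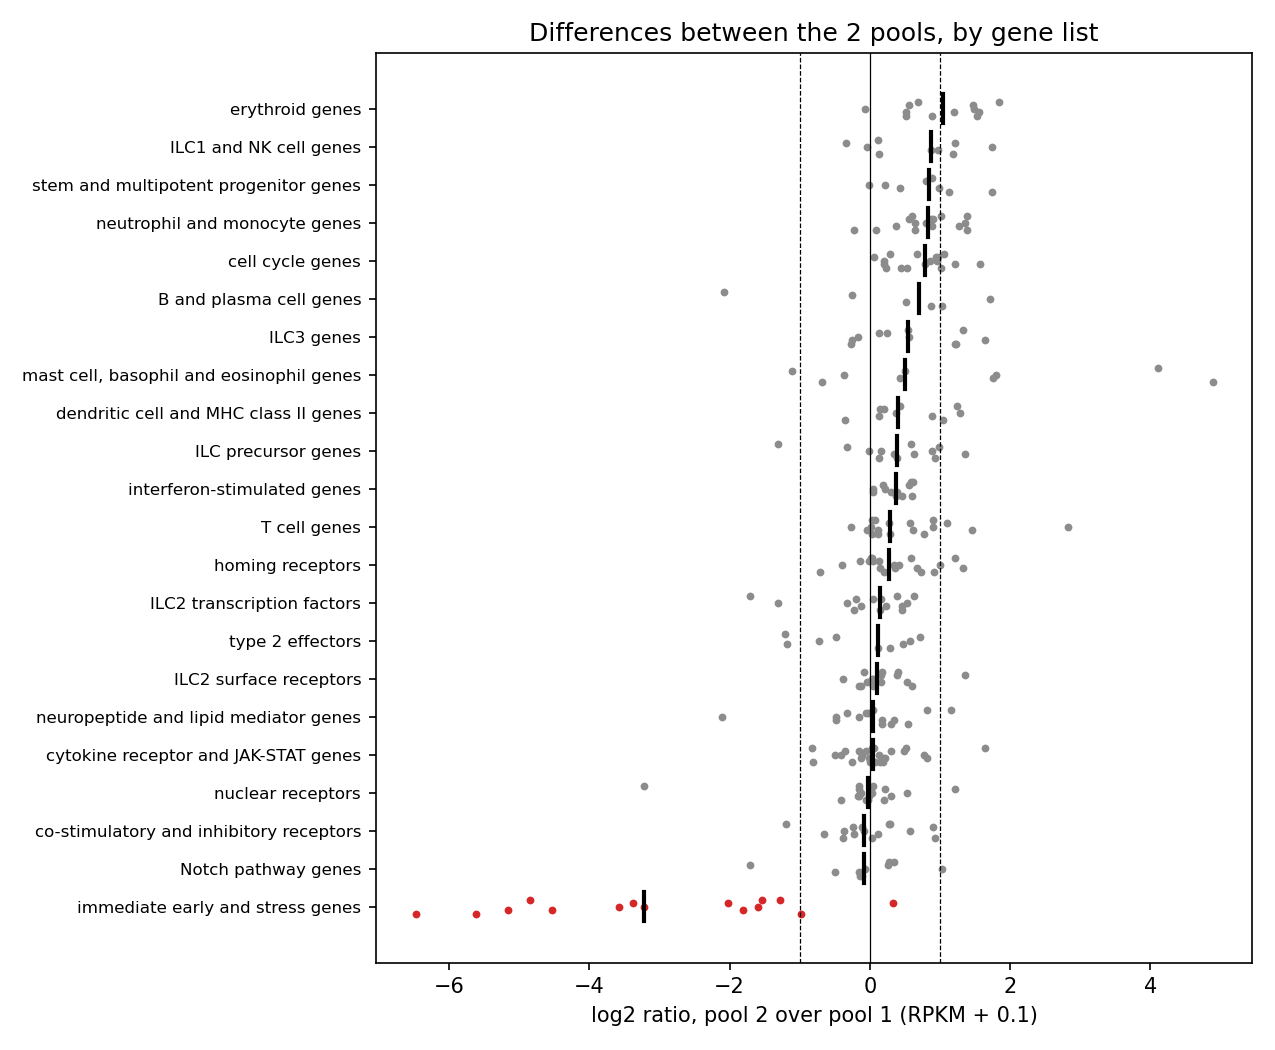
Log2 ratio of pool 2 over pool 1 (RPKM + 0.1) for the detected members of each list with more than 1 detected member. Points are genes, bars are list medians and dashed lines are 2-fold differences. The immediate early list (red, median -3.22) lies toward pool 1 and the erythroid list (1.04) farthest toward pool 2.

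The pools also differed in sex-chromosome genes. The X-inactivation transcript Xist was at 11.1 RPKM in pool 1 and 3.89 in pool 2, and the Y-linked gene Ddx3y at 0.267 RPKM in pool 1 and 9.52 in pool 2. Eif2s3y, another Y-linked gene, had 3 reads in pool 1 and 634 in pool 2, a ratio of 215 (95% counting interval 73.4 to 1047). Kdm5d had 0 and 270 reads and was at least 91.7-fold higher in pool 2 against a floor of 3 reads in pool 1. Zfy1 was listed at 0 in both pools. Intervals and floors cover counting error only.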

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

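Of 1173 values recomputed under alternatives, 1057 counted as unchanged. For ratios and list shifts this meant the same side of the threshold, with direction checked only where the main value had passed it. Lineage differences also had to keep their sign. Counts had to stay within 1.5-fold of the main count, and other values within their spread or bootstrap interval. Another 84 moved, 18 passed no longer, 11 newly passed and 3 reversed. Some alternatives were chosen after seeing the data: the filter of 1 RPKM in either library, the likelihood on reads and shares of estimated reads. So were pseudocounts 0.01 and 1 for differences between pools. The exact binomial test was planned for read counts, and its use on recovered reads as an alternative was chosen after seeing the data. The 282 genes apart became 102 at 5 RPKM, 441 at 10 reads, 1535 without a filter, 588 at 1 RPKM in either library and 81 in an exact negative binomial test with an assumed coefficient of variation of 0.2; filters change which low genes are tested. Those higher in pool 2 (176) became 272 at 0.5 RPKM, 59 at 5 RPKM, 330 at 10 reads and 379 in either library, and those higher in pool 1 (106) 43 at 5 RPKM and 209 in either. The correlation was 0.976 at 5 RPKM and 0.985 at 10 reads, and the coefficient of variation 0.217 at 0.5 RPKM, 0.161 at 5 RPKM, 0.215 at 10 reads and 0.172 from reads. The mean in place of the median gave 6.77 for ILC2 surface receptors. In CPM, ILC2 transcription factors had a median of 7.30 and surface receptors 8.16, and the identity genes exceeded T cell, neutrophil and erythroid genes by 1.46, 2.61 and 2.64. With surface receptors alone these were 1.77, 1.87 and 2.81 and passed, and with transcription factors alone the first 2 reversed to -0.18 and -0.090; over their alternatives the adjusted permutation p ran from 0.00898 to 1, 0.00279 to 1 and 0.00833 to 0.390. The other 7 lineage differences passed under every alternative run, with adjusted permutation p up to 0.0359 for ILC3 genes. The Gata3 to Eomes ratio was 11.80 with pseudocount 0.01, 7.99 with 1 and 11.30 in CPM. The shift of the Y-linked list reversed to 4.28 at 10 reads, where Y-linked genes join Xist. Beyond the filters and list members, the cause was not tested. Leaving out either library changed no call of the 10 lineage comparisons and no direction of the Gata3 ratios. Among list levels, 11 of 48 moved by more than their spread. That spread is the SD over the same 2 pools, and a mean of both cannot move past it when 1 is left out. Staying within it therefore shows no stability for such means. Differences between the pools cannot be computed from 1 library. No paired analysis was possible because there is 1 group. The planned count models were replaced or not run on RPKM, and genes under about 3 reads cannot be ranked at this depth.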

Other observations

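In this part, the test of 6 further gamma delta T cell genes and that of the X-linked homologues were set before their values were seen, and the other tests were chosen only after the result was seen, as were the genes of the next paragraph.

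Several genes outside the immediate early list, picked by their ratio, were higher in pool 1. The kinase gene Sik1 was 7.81-fold higher at 99.9 against 12.7 RPKM, the transcription factor Klf4 6.39-fold, the NF-kappa B regulators Nfkbiz 6.09-fold, Nfkbid 5.54-fold and Tnfaip3 3.13-fold, Gadd45b 4.11-fold and the early activation marker Cd69 2.89-fold. The feedback inhibitors of cytokine signalling Socs3, Cish, Socs1 and Socs2 differed less, with pool 1 to pool 2 ratios of 1.77, 1.75, 1.41 and 1.28. Hes1, a transcription factor on the Notch and ILC2 lists, was at 10.2 RPKM in pool 1 and 3.02 in pool 2, and Il18r1, an IL-18 receptor chain of ILC precursors, at 17.8 RPKM in pool 1 and 45.8 in pool 2. The steroid-forming enzyme Cyp11a1 was 8.95-fold higher in pool 2, Ly6c1 4.20-fold and the mitochondrial transhydrogenase Nnt 2.23-fold at 34.8 against 15.6 RPKM. The B lineage factor Pax5 had 3 reads in pool 1 and 122 in pool 2, a ratio of 41.4 (95% counting interval 13.9 to 204).

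Immediate early genes made up 2.14% of the summed RPKM in pool 1 and 0.165% in pool 2. A few abundant genes taking the reads of pool 2 would lower all other genes there alike, and this is argued against, since the median log2 ratio of the 11013 detected genes was 0.044 beside -3.22 for the list. RNA of other cell types in pool 1 cannot be told apart as a source: the largest excess of a listed marker in pool 1, that of Ltb, was 8.36% of the excess of Fos, but the level of Fos in such cells is not known, and 6 markers of other lineages were over 4-fold higher in pool 1, among them Col1a1 (41.1-fold), Col1a2 (34.1-fold), Sparc (15.3-fold), Igj (17.3-fold) and Igkc (4.24-fold). Stimulation or handling of the cells before lysis also stays open as a candidate explanation, because the time from marrow to lysis is not given in the sources used here and the evidence is mixed: the detected effectors had a median log2 ratio of 0.12 with Il5 and Areg at -1.18 and -1.22, which are under 2-fold with pseudocount 1 (-0.84 and -0.987), and of 6 heat shock genes Hspb1 was at 1.42, Hspa1a at 0.76, Dnajb1 and Hspa1b at 0.33, Hsph1 at 0.055 and Hsp90aa1 at -0.046. The labels name no biological difference between the pools, so none was tested for this pattern.

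Some genes of gamma delta T cells were higher in pool 2 and others were not. Beside Tcrg-V6 and Cd163l1, the constant region Trdc was 7.06-fold higher at 130.4 against 18.4 RPKM and the kinase gene Blk 6.10-fold. The receptor segments Trdv5, Trgv2, Trdv4 and Tcrg-V4 and the constant region Tcrg-C2 had log2 ratios of 2.84, 1.74, 1.47, 1.40 and 0.83, and 5830411N06Rik 1.67, while the more abundant constant regions Tcrg-C1 and Tcrg-C4 had log2 ratios of -0.50 and -0.68 and Il17a had 0 and 1 reads. The hypothesis that pool 2 may hold gamma delta T cells of the kind that makes IL-17 was tested on 6 further genes, whose median log2 ratio was 0.93, at the 99.99th percentile of matched random lists. Sox13, Actn2, Il17re and Serpinb1a were higher in pool 2, at 2.62, 1.70, 0.98 and 0.87, but the abundant Tmem176a and Tmem176b were at 0.082 and 0.036. The erythroid, ILC1 and NK, and neutrophil lists, with medians of 1.04, 0.88 and 0.83, also lay above all matched random lists. The test therefore does not single out gamma delta T cells. A lower share of ILC2 progenitors with every other cell type raised alike is argued against: of 117 markers of other lineages at 1 RPKM or more in either pool, 6 were over 4-fold lower in pool 2, all on the stromal and plasma cell lists, and 4 over 4-fold higher. These counts do not exclude a lower share with other cell types raised unequally, and most other lineage lists shifted toward pool 2. ILC3 stay open as a further source, since the ILC3 list had a median log2 ratio of 0.54, or 0.25 and within the random lists at 5 RPKM or more, and gene totals do not separate rearranged from germline receptor transcripts. The antibodies of the sort, which could have removed T cells, are not given in the sources used here.

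Y-linked genes were higher in pool 2 and Xist in pool 1. Reads of X-linked homologues counted on the Y-linked genes are argued against, since the median absolute log2 ratio of Ddx3x, Kdm6a, Kdm5c and Eif2s3x was 0.17. The hypothesis that the pools may hold different shares of male mice was not tested independently: 4 of 4 Y-linked genes with 10 or more reads were over 4-fold higher in pool 2, which restates the pattern. For Xist alone, a lower yield of nuclear RNA in pool 2 stays open, because the nuclear RNA Malat1 had a log2 ratio of -1.19 beside -1.49 for Xist. The sex of the mice is not given in the sources used here, so different shares of male mice remain a hypothesis. If the shares do differ, sex cannot be told apart from the other differences between the pools.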
